A study of Homo sapiens with 6 samples.

How the data were processed

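RNA was extracted with Trizol from A375 melanoma cells grown in DMEM with serum, and libraries were made with a stranded total RNA kit from Illumina, per the labels' protocols. The series held 6 samples, 3 treated with 1 µM BMH-21 for 6 h and 3 controls, and the labels call the replicates biological. Groups were taken from the sample titles and treatment labels. The authors deposited 1 table of FPKM values with 25548 gene rows and 3 columns per group, and the submitters' processing notes name TopHat2, Cuffdiff 2.0 and the genome build GRCh37. The notes give neither the role of each tool nor its settings, and the gene annotation is not given in the sources used here. FPKM divides fragment counts by transcript length and library size, so it holds no read totals, and it becomes unreliable for genes shorter than a fragment.

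The 3 columns of each group were compared before any difference was computed. Within a relative tolerance of 0.0001, the first column was the midpoint of the others in 99.9% of rows with all values above 0, in both groups. Where the second column was 0, the third was at least 2 times the first in 99.9% of rows. The first column was therefore read as the FPKM estimate of the group and the others as the authors' lower and upper bounds, although the table titles them as replicates. Which confidence level the bounds stand for, and how the 3 libraries entered the estimate, is not given in the sources used here. In 12 rows, the same ones in both groups, the estimate lay outside its bounds; 11 of them were measured and are neither counted as separate nor as overlapping. The bounds extended by a median of 22.1% of the control estimate between 1 and 10 FPKM, 18.9% between 10 and 100 FPKM and 18.1% at 100 FPKM or more, and by 22.1%, 18.7% and 18.1% in BMH-21. Estimates summed to 781555 FPKM in control and 798627 FPKM in BMH-21, of which short RNA rows took 28.2% in each.

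The design written before the data were examined was a limma fit on log2(FPKM + 1) over 6 libraries, with camera over gene lists. It could not be run on columns that are not libraries. Its stated fallback for values given only per group was used, in which no test is made and the authors' values are given. The half-widths, the separation of intervals, the bootstrap intervals and the random lists described below are not part of that written design. The difference of a gene was log2(FPKM + 1) in BMH-21 minus that in control, on the authors' scaling. Its half-width was the square root of the summed squares of both groups' half-widths on the log2 scale. A gene counted as measured at 1 FPKM or more in at least 1 group, which 13074 rows met. Intervals were called separate where the lower bound of one group lay above the upper bound of the other. The "at least 2-fold" counts are on the log2(FPKM + 1) scale, while folds printed for single genes are ratios of the FPKM estimates. Overlap or separation of intervals describes the table and is no replicate test. Intervals can overlap although the difference exceeds its half-width, as for MDM4, RPL22L1, BYSL, POLR2A and TAF1C, so overlap does not mean no change.

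Genes were named by a rule fixed before the data were examined. It takes 17 genes of the RNA polymerase I and p53 axis, the 8 genes furthest above and the 8 furthest below control, and up to 2 members per list and direction, all by size of difference since no test was possible. Values of 3 genes that the rule names are not reported here. Rows that join several symbols were left out of the 8. Rows of snoRNA, microRNA, snRNA, rRNA and other RNA genes shorter than a library fragment were left out by symbol. The vault RNA and SNAR rows were added to that exclusion because they meet its wording, although the listed prefixes do not include them. The 325 measured rows so defined are called short RNA rows. BBC3 and SESN2 are named beside the p53 list because the rule names them through the apoptosis and ATF4 lists.

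The 44 gene lists were fixed from textbook knowledge before the data were examined. They cover p53 targets, RNA polymerase I, II and III, ribosome biogenesis, cytosolic and mitochondrial ribosomal proteins, ribosomal RNA genes, snoRNA hosts, MYC targets, melanocyte differentiation, undifferentiated melanoma, YAP targets, ERK output, immediate early genes, NF-kappaB, interferon, antigen presentation, ATF4, the unfolded protein response, heat shock, NRF2, G1/S, mitosis, histones, DNA repair, apoptosis, splicing, the mitochondrial genome, respiratory chain, sterols, hypoxia, autophagy, TGF-beta, the clock, chromatin, reference genes, markers of 4 other cell types, ZNF-named genes, snoRNAs and microRNAs. Several lists share members. A list with at least 5 measured members was described by its counts, its median difference, a bootstrap 95% interval of that median over its members (2000 draws) and the percentile of the median among 10000 random lists of the same size, drawn from the measured rows within 20 bins of mean level. The percentile describes these estimates, carries no replicate error and does not allow for correlation between genes of a list.

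The steps were tested on simulated data with 12441 genes, of which 200 were set to differ, under the assumption that the bounds stand for 2 standard deviations. Intervals were read as separate for 56% of genes set 1.5-fold apart, 80% at 2-fold, 96% at 4-fold and 98% at 8-fold, and for 0.466% of 12241 unchanged genes. Alternatives were a pseudocount of 0.1 or 0.01, no filter, a filter of 5 FPKM, and rescaling to the same sum, the same median or the same quantiles. Leaving out short RNA rows, a filter of 10 FPKM, and the same sum for list medians were added after the data were seen. Gene names and lengths came from GENCODE release 29, which is built on another assembly than the one the submitters name, so no coordinates are given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.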

Results

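Gene expression was measured by RNA sequencing in A375, an established human melanoma cell line that carries mutant BRAF. The cells received BMH-21, a small molecule that inhibits RNA polymerase I, the enzyme that transcribes the ribosomal RNA genes in the nucleolus. The labels give 6 samples in 2 groups, 3 treated with 1 µM BMH-21 for 6 h and 3 controls that received the solvent DMSO and are titled 0 h. For each of 25548 gene rows the deposited table gave 3 values per group in FPKM (fragments mapped to a transcript, divided by its length and by the size of the library). Although titled as replicates 1 to 3, the values behaved as 1 FPKM estimate with a lower and an upper bound. The first value lay at the midpoint of the others in 16203 of 16213 control rows and 15872 of 15881 BMH-21 rows in which all were above 0. Values of single libraries were therefore not analysed here, the spread between replicates could not be computed, and no p-value is given for any difference. The bounds are the authors' own interval, whose confidence level is not given in the sources used here. Genes whose intervals did not overlap are called separate below as a description of the table, not as a test. The sequencing depth was unknown, because FPKM values hold no read totals. Estimates of at least 1 FPKM were listed for 12761 rows in control and 12767 rows in BMH-21, and the median interval extended 18.9% to either side of the control estimate for genes between 10 and 100 FPKM, against 22.1% between 1 and 10 FPKM and 59.7% between 0.1 and 1 FPKM.

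The comparison of BMH-21 with control asked which transcripts differ in melanoma cells after 6 h with the drug. Inhibition of RNA polymerase I itself was not measured. Because all controls are titled 0 h, the effect of BMH-21 could not be told apart from that of 6 h of further culture. The words "with BMH-21" below cover both. CDKN1A, which encodes the cell cycle inhibitor p21, was 9.81-fold higher with BMH-21, at 329 FPKM against 33.5 FPKM in control. MDM2, which encodes the ubiquitin ligase that degrades p53, was 9.12-fold higher, at 315 FPKM against 34.6 FPKM. CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor, stood furthest apart of all genes other than short RNAs, at 201 FPKM (bounds 165 to 236) against 2.0 FPKM (bounds 1.51 to 2.49). In the other direction AMACR, an enzyme of branched-chain fatty acid oxidation, was 4.38-fold lower, at 6.25 FPKM (bounds 4.90 to 7.60) against 27.4 FPKM (bounds 22.2 to 32.6). Among 12749 genes measured at 1 FPKM or more in at least 1 group, rows of short RNAs left out, 116 were higher and 33 lower by at least 2-fold on the log2(FPKM + 1) scale. Intervals were separate for 456 higher and 400 lower genes and overlapped for 11882 genes, or 93.2%. With the 325 short RNA rows included, 223 rows were higher and 86 lower by at least 2-fold, and 534 higher and 446 lower rows had separate intervals. The median absolute log2 difference of the genes other than short RNAs was 0.17, below the median half-width of 0.37 that the bounds gave such a difference.

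**Figure D1:**
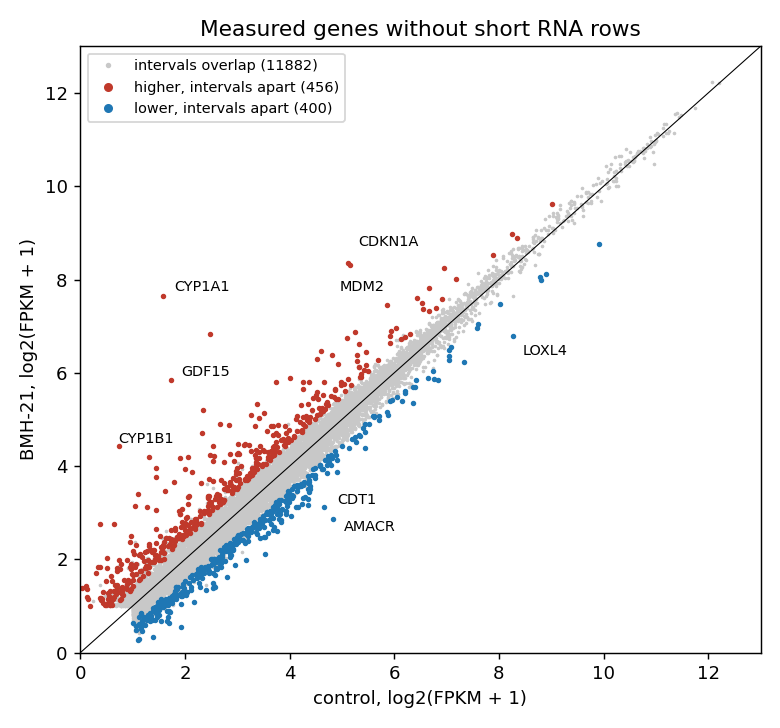
Level of each measured gene in control (horizontal axis) and BMH-21 (vertical axis) as log2(FPKM + 1), short RNA rows and the 11 rows with unusable bounds left out; each point is 1 gene, coloured by whether the deposited intervals of the groups overlapped, and the line marks equal levels. The 456 higher genes lie above the line, with CYP1A1 furthest from it, and the 400 lower genes lie below it.

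The 8 genes furthest above control by log2 difference were CYP1A1, LOC100653010, GDF15, TAC1, CDKN1A, MDM2, CYP1B1 and BTG2. GDF15, a secreted stress cytokine, was at 56.3 FPKM against 2.32 FPKM, a log2 difference of 4.11 ± 0.63, where the value after the sign is the half-width combined from the bounds of both groups. LOC100653010 matched no gene of the reference used for names, and it was at 113 FPKM against 4.58 FPKM. Its fold of 24.7 lay close to the 24.3 of GDF15, and whether these 2 rows are independent was not tested. TAC1, the precursor of substance P, was at 20.7 FPKM against 0.659 FPKM. CYP1B1, another cytochrome P450 enzyme controlled by the aryl hydrocarbon receptor, was 11.7-fold higher, at 17.4 FPKM against 1.49 FPKM. BTG2, an antiproliferative gene, was 8.89-fold higher, at 36.1 FPKM against 4.05 FPKM. Among the 8 genes furthest below control after AMACR, IGFBP5, which encodes an insulin-like growth factor binding protein, was 3.14-fold lower, at 7.72 FPKM against 24.3 FPKM. LOXL4, a lysyl oxidase that crosslinks collagen, was 2.81-fold lower, at 109 FPKM against 306 FPKM. The homeobox gene HOXB8 was at 3.31 FPKM against 10.5 FPKM, and CDT1, which licenses replication origins, was at 7.93 FPKM against 19.5 FPKM. The phosphatase gene PTP4A3 was at 0.466 FPKM against 2.81 FPKM, the non-coding LOC100128822 (LINC01003) at 2.07 FPKM against 5.98 FPKM and HPDL at 2.95 FPKM against 7.94 FPKM. All of these intervals were separate. Log2 differences of genes at low level depended on the pseudocount of 1, which understates them.

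**Figure D2:**
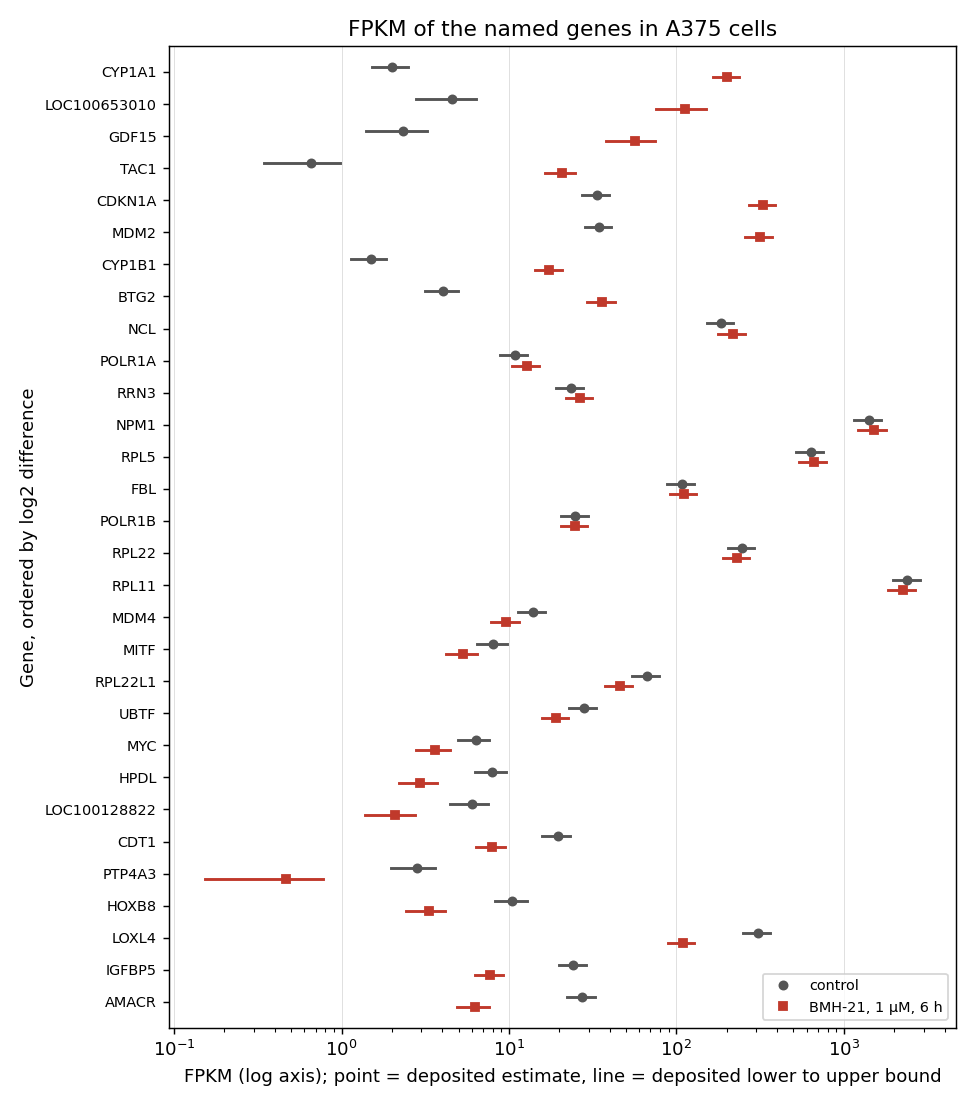
Deposited FPKM of the genes named for their place in the RNA polymerase I and p53 pathways or for the size of their difference, on a log axis; circles are control and squares BMH-21, and each line runs from the deposited lower to the upper bound, with genes ordered by log2 difference. CDKN1A and MDM2 stand at 33.5 and 34.6 FPKM in control and at 329 and 315 FPKM with BMH-21, while the intervals of POLR1A, POLR1B, RPL5 and RPL11 overlap.

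Direct targets of p53, the transcription factor that halts the cell cycle after DNA damage or nucleolar stress, were higher with BMH-21 nearly throughout. Of 37 measured targets, 32 were higher with separate intervals, none was lower and 5 overlapped, and 23 were higher by at least 2-fold. GDF15, CDKN1A and MDM2 led the list, which also held BBC3, a killer protein of the BCL2 family that was 5.37-fold higher at 28.8 FPKM against 5.36 FPKM, and SESN2, a sestrin that restrains mTORC1, 3.87-fold higher at 17.7 FPKM against 4.58 FPKM. At the low end NINJ1 was at 12.4 FPKM against 13.1 FPKM and KITLG at 1.19 FPKM against 1.18 FPKM, both with overlapping intervals. MDM4, a partner of MDM2 that restrains p53, was at 9.64 FPKM against 13.9 FPKM. Its intervals overlapped, although its log2 difference (-0.49 ± 0.35) exceeded the half-width. The list's median log2 difference was 1.27, with a bootstrap 95% interval over its members of 0.96 to 1.58. It lay above all 10000 random lists of the same size and level, the middle 95% of which had medians between -0.04 and 0.13. Of the 108 genes other than short RNAs that were higher by at least 2-fold with separate intervals, 23 belonged to this list, and of the 33 that were lower, 0 did. The list held 40 genes, and targets of p53 outside it are not part of this count.

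Messenger RNAs of the RNA polymerase I apparatus differed by less than 1.5-fold in the members named here. UBTF, the factor that keeps ribosomal DNA open for transcription, was 1.46-fold lower with BMH-21, at 19.2 FPKM (bounds 15.7 to 22.7) against 28.0 FPKM (bounds 23.0 to 33.1), and was the only member of 17 with separate intervals, by a narrow margin. POLR1A, the largest subunit, was at 12.8 FPKM against 10.8 FPKM, POLR1B at 24.9 FPKM in both groups and the initiation factor RRN3 at 26.6 FPKM against 23.4 FPKM. The other extremes of the list were TAF1C, at 18.8 FPKM against 13.4 FPKM, and POLR1D, at 54.3 FPKM against 73.6 FPKM, both with overlapping intervals, which do not show equal levels. The list's median of 0.05 stood at percentile 43.8 of the random lists and turned to -0.04 under quantile normalization. No member of 12 RNA polymerase II subunits was separate (median 0.20, percentile 97.3), although POLR2A was at 16.8 FPKM against 11.9 FPKM, and this list moved just above the middle 95% without short RNA rows, to percentile 98.1, and under quantile normalization, to percentile 97.7. None of 22 RNA polymerase III genes was separate either (median 0.07, percentile 62.3), with GTF3C6 highest at 52.0 FPKM against 38.7 FPKM. The 10 listed nuclear ribosomal RNA genes and the 15 listed genes of the mitochondrial genome matched no row and were not analysed here.

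Factors that process pre-ribosomal RNA and assemble ribosomes had a median log2 difference of 0.12 over 80 genes, at percentile 98.0, with 79 of them overlapping. WDR43, a component of the small subunit processome, was the 1 separate member, at 65.1 FPKM against 44.0 FPKM, and BYSL followed at 17.7 FPKM against 12.1 FPKM. The nucleolar proteins nucleolin (NCL, 217 FPKM against 185 FPKM), fibrillarin (FBL, 112 FPKM against 108 FPKM) and nucleophosmin (NPM1, 1504 FPKM against 1409 FPKM) all overlapped. Of 83 cytosolic ribosomal protein genes, RPS27L, which also lies under p53 control, was the 1 separate member, 2.23-fold higher at 225 FPKM against 101 FPKM. RPL5 and RPL11, which with 5S ribosomal RNA bind MDM2, were at 659 FPKM against 632 FPKM and at 2247 FPKM against 2398 FPKM. RPL22 was at 232 FPKM against 246 FPKM and its paralog RPL22L1 at 45.9 FPKM against 66.3 FPKM, overlapping in both cases. The log2 difference of RPL22L1 (-0.52 ± 0.37) exceeded its half-width all the same, while that of RPL22 (-0.09 ± 0.37) did not. The cytosolic list had a median of 0.04, below random lists of like level (percentile 0.415), and the median turned to -0.06 under quantile normalization. Mitochondrial ribosomal protein genes had a median of 0.13 over 77 members (percentile 98.4) and no separate member, with MRPL39 at 45.4 FPKM against 34.3 FPKM and MRPL12 at 46.3 FPKM against 61.8 FPKM. Under quantile normalization the ribosome assembly, cytosolic and mitochondrial lists all lay within the middle 95% of random lists. Among 13 non-coding snoRNA host genes none was separate (median 0.12, percentile 73.2), GAS5 being at 283 FPKM against 339 FPKM. MYC, the growth regulator, was 1.75-fold lower with separate intervals, at 3.61 FPKM against 6.32 FPKM, while none of 30 MYC targets outside the ribosome lists was separate (median 0.14, percentile 90.2). ODC1, a MYC target in polyamine synthesis, was at 41.7 FPKM against 31.0 FPKM.

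Most genes of DNA replication and the G1/S transition had lower estimates with BMH-21. Of 43 measured members, 36 had a negative log2 difference, 9 were lower with separate intervals, 1 was higher and 33 overlapped. CDT1 was 2.46-fold lower, and E2F2, an activator of S-phase genes, was 2.81-fold lower at 1.53 FPKM against 4.29 FPKM. E2F7, a repressor of the same gene programme that is also a p53 target, was the higher member, 2.61-fold above control at 18.2 FPKM, and the replication clamp PCNA was at 170 FPKM against 133 FPKM with overlapping intervals. The list's median of -0.28 (bootstrap interval -0.40 to -0.21) lay below all 10000 random lists. Of 48 mitotic genes none was separate, and their median of 0.03 (percentile 22.3) turned to -0.03 under quantile normalization, with AURKA at 78.7 FPKM against 62.0 FPKM and AURKB at 43.4 FPKM against 52.6 FPKM. Of 40 replication-dependent histone genes, 3 were higher, 1 was lower and 36 overlapped (median 0.04, percentile 3.95, turning to -0.10 under quantile normalization). The linker histone genes HIST1H1A and HIST1H1E parted, the first 2.51-fold higher than its control level of 38.9 FPKM and the other 2.23-fold lower at 433 FPKM against 964 FPKM. DNA repair genes had a median of -0.13 over 42 members (percentile 0.06), with 2 higher, 1 lower and 39 overlapping. The higher members were RAD51C, a homologous recombination gene, at 45.2 FPKM against 23.8 FPKM and the translesion polymerase subunit REV3L at 13.3 FPKM against 6.84 FPKM.

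Of 28 genes of melanocyte differentiation, 15 were measured, of which 3 were lower with BMH-21, 1 was higher and 11 overlapped. The pigment genes TYR, TYRP1, DCT, PMEL and MLANA were under 1 FPKM in both groups. MITF, the transcription factor that governs the pigment lineage, was 1.52-fold lower at 5.31 FPKM (bounds 4.20 to 6.42) against 8.06 FPKM (bounds 6.45 to 9.68), narrowly separate, and the calcium-binding protein gene S100B was 1.61-fold lower at 17.8 FPKM against 28.7 FPKM. RAB38, a GTPase of melanosome transport, went the other way at 22.5 FPKM against 13.3 FPKM. The lineage factors SOX10, with an estimate 1.08-fold lower, and PAX3, at 8.19 FPKM against 7.02 FPKM, overlapped. The median of the 15 was -0.31, at percentile 0.01. The genes under 1 FPKM and SOX10 were named after their values were seen. Genes of the undifferentiated, AXL-high melanoma state had 3 higher, 1 lower and 19 overlapping members of 23 (median -0.04, percentile 7.71). THBS1, which encodes thrombospondin, was 2.45-fold higher at 302 FPKM against 123 FPKM, WNT5A was at 19.2 FPKM against 10.2 FPKM and PDGFRB at 2.54 FPKM against 4.21 FPKM. Among 20 genes of ERK pathway output, 3 were higher, 1 was lower and 16 overlapped (median 0.02, percentile 22.3, below 0 under each of 3 other scalings). The cytokine gene LIF was 3.91-fold higher at 33.4 FPKM against 8.54 FPKM, and the feedback inhibitor SPRY4 was at 41.5 FPKM against 61.3 FPKM. Of 19 YAP and TEAD targets, 1 was lower and 18 overlapped (median -0.08, percentile 4.02), the lower one being ANKRD1 at 0.978 FPKM against 1.80 FPKM. Of 21 TGF-beta and SMAD targets, 2 were higher, 1 was lower and 18 overlapped (median 0.03, percentile 45.0, turning to -0.01 under quantile normalization), with ID2 at 2.59 FPKM against 1.06 FPKM and ID1 at 56.7 FPKM against 84.5 FPKM.

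Cytosolic chaperones of the heat shock response had a median of 0.30, above all random lists, with 2 of 20 genes higher, 0 lower and 18 overlapping. The highest were HSPA4L at 8.07 FPKM against 3.17 FPKM and HSPH1 at 98.4 FPKM against 59.8 FPKM, and DNAJB1 was lowest at 44.0 FPKM against 57.7 FPKM. Of 20 targets of the antioxidant factor NRF2, 4 were higher, 0 lower and 16 overlapped, with a median of 0.27 at percentile 99.98. OSGIN1 was at 3.43 FPKM against 1.58 FPKM and TXNRD1, which encodes thioredoxin reductase, at 160 FPKM against 100.4 FPKM. Immediate early genes had 6 higher, 1 lower and 23 overlapping members of 30 (median 0.25, percentile 99.98), and ATF3, a stress-induced transcription factor, was 8.44-fold higher at 14.6 FPKM against 1.72 FPKM. Targets of ATF4, which drives amino acid supply under stress, split: 7 of 32 were higher, 2 were lower and 23 overlapped. Their median of -0.05 (percentile 1.21) and mean of 0.20 had opposite signs, and with only genes at 5 FPKM or more the percentile was 4.73. ATF3 and SESN2 were the highest members, and CEBPG (5.38 FPKM against 9.60 FPKM) and the alanyl-tRNA synthetase AARS (48.1 FPKM against 72.5 FPKM) the lowest. In the unfolded protein response of the endoplasmic reticulum 0 of 20 genes were higher and 2 were lower (median -0.01, percentile 7.11), namely XBP1, a transcription factor of this response, 1.70-fold lower than its control level of 34.0 FPKM and HERPUD1 1.64-fold lower than its control level of 21.4 FPKM.

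Apoptosis genes of the BCL2 and caspase families held 5 higher, 0 lower and 22 overlapping members of 27 (median 0.14, percentile 97.3). BBC3 and BAX, both also on the p53 list, were the highest, BAX at 118 FPKM against 60.4 FPKM. Without the 3 members shared with the p53 list, 3 of 24 were higher. The list lay above the middle 95% of random lists under quantile normalization, at percentile 98.6, and with genes at 5 FPKM or more, at percentile 98.1. Of 25 NF-kappaB targets and cytokines, 5 were higher, 1 was lower and 19 overlapped (median -0.02, percentile 30.4), with LIF and the growth factor CSF1 (9.18 FPKM against 3.24 FPKM) highest and the adaptor TRAF1 (1.80 FPKM against 4.77 FPKM) lowest. Interferon-stimulated genes had 1 higher, 1 lower and 26 overlapping members of 28 (median -0.10, percentile 3.28). TAP1, a peptide transporter, was at 20.1 FPKM against 11.9 FPKM and IFI44 at 5.12 FPKM against 8.17 FPKM. TAP1 was also the 1 separate gene of 17 in MHC class I presentation (median 0.11, percentile 80.7). Of 29 autophagy and lysosome genes 1 was higher, 1 lower and 27 overlapped (median 0.15, percentile 97.6), with the protease gene CTSL1 at 70.4 FPKM against 43.2 FPKM and WIPI1 at 7.83 FPKM against 12.2 FPKM. Among 25 hypoxia and glycolysis genes 3 were higher and 0 lower (median 0.14, percentile 92.9), including the glucose transporter SLC2A1 at 86.1 FPKM against 43.2 FPKM and ANGPTL4 at 5.17 FPKM against 2.49 FPKM.

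The remaining lists held few separate genes. Of 12 clock genes, ARNTL was higher at 4.30 FPKM against 2.43 FPKM and 11 overlapped, with a median of -0.22 at percentile 1.10. Among 39 splicing regulators SRSF8 was higher, at 18.8 FPKM against 9.73 FPKM, and SRSF3 lower, at 89.1 FPKM against 132 FPKM (median 0.06, percentile 41.1, turning to -0.03 under quantile normalization). The acetyltransferase KAT2B, at 11.9 FPKM against 8.06 FPKM, was the 1 separate gene of 35 chromatin modifiers (median 0.08, percentile 82.6). No gene was separate among 42 nuclear-encoded respiratory chain subunits (median 0.11, percentile 75.3) or 20 abundant reference genes (median 0.12, percentile 72.1), and both medians turned to -0.02 and -0.01 under quantile normalization. NDUFB9 was at 307 FPKM against 246 FPKM and VIM at 1017 FPKM against 1102 FPKM. None of 22 sterol synthesis genes was separate (median -0.01, percentile 11.3), HSD17B7 being at 9.89 FPKM against 8.24 FPKM. Genes named ZNF, most of which encode zinc finger proteins, had 11 higher, 2 lower and 421 overlapping members of 434, and their median of 0.10 lay above all random lists. ZNF79 was at 6.84 FPKM against 2.76 FPKM and ZNF367 at 5.17 FPKM against 11.8 FPKM. Of 37 lists with at least 5 measured members, the snoRNA and microRNA lists not counted, 8 lay above the middle 95% of random lists, 6 below and 23 inside. If the lists were independent, which shared members prevent, and genes within a list varied independently, chance alone would put 1.85 of them outside. The random lists do not keep any correlation between genes of a list, so these counts cannot be read as an excess over chance.

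**Figure D3:**
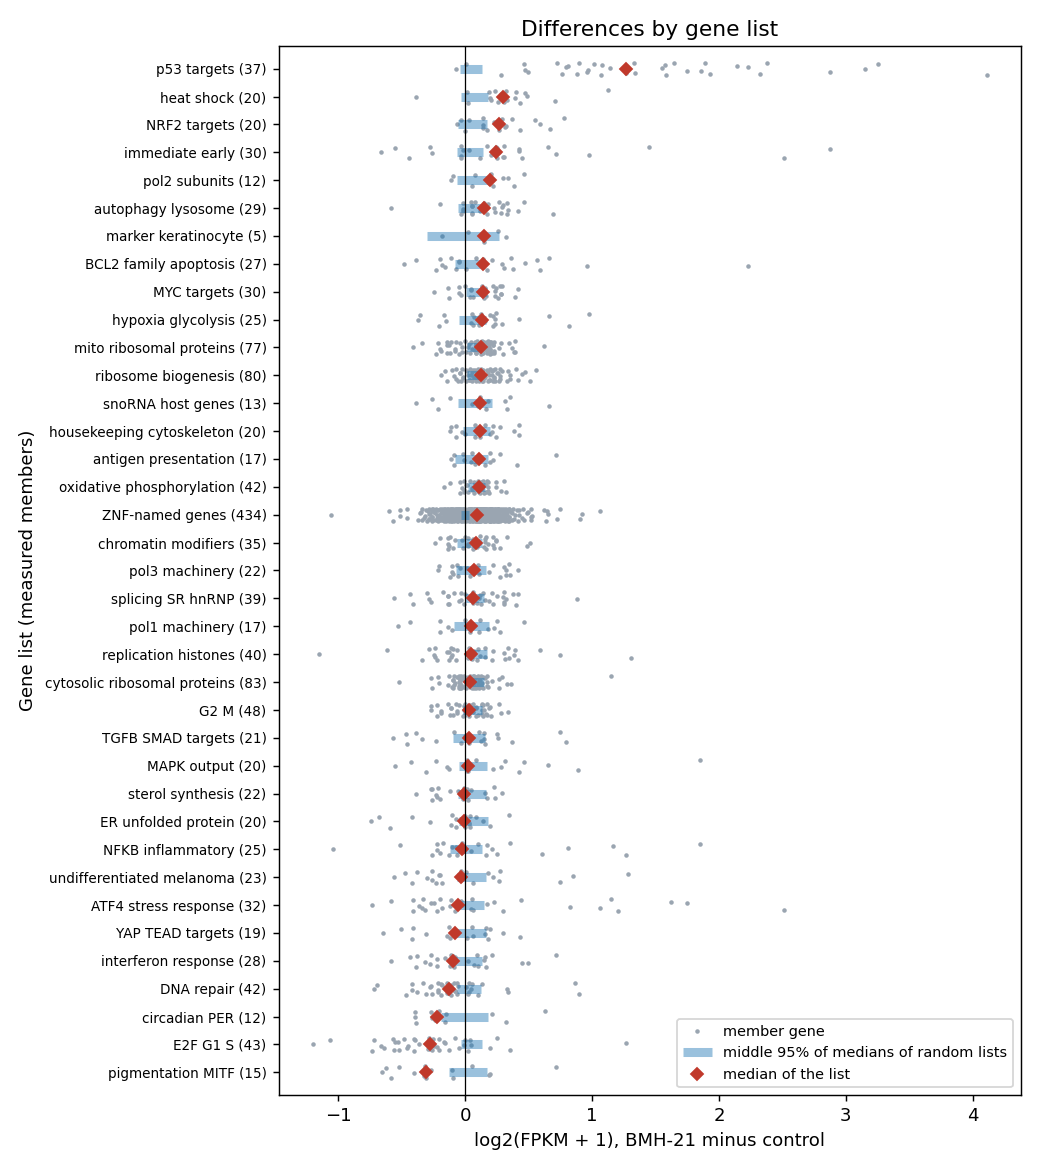
Log2 difference of FPKM + 1, BMH-21 minus control, for each gene list with at least 5 measured members, the snoRNA and microRNA lists left out; grey points are member genes, red diamonds list medians and blue bars the middle 95% of the medians of 10000 random lists matched on level. The p53 targets have the highest median, 1.27, and the melanocyte differentiation and G1/S lists the lowest, -0.31 and -0.28.

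Markers of other cell types reached at most 14.7 FPKM. Of 5 keratinocyte markers measured none was separate (median 0.15, percentile 87.9), and KRT10 was the most abundant at 10.6 FPKM against 10.4 FPKM. Of the fibroblast, endothelial and leukocyte markers 4, 2 and 2 were at 1 FPKM or more, too few to describe as lists. Their most abundant members were LUM at 5.23 FPKM against 2.34 FPKM, TIE1 at 2.62 FPKM against 2.69 FPKM and CD68 at 9.96 FPKM against 14.7 FPKM. LUM was higher with separate intervals, as were the fibroblast marker DCN, 5.97-fold above its control level of 0.419 FPKM, and the endothelial marker ESAM, 2.55-fold at 1.59 FPKM against 0.625 FPKM, both named after their values were seen. Of the other fibroblast markers PDGFRB was lower, and the collagen gene COL1A1 was at 0.459 FPKM against 0.598 FPKM. Rows of small nucleolar and microRNAs varied widely. Of 214 snoRNA rows 34 were higher, 21 lower and 159 overlapping (median 0.43), and of 80 microRNA rows 39 were higher, 17 lower and 24 overlapping (median 0.96), with both medians above all random lists. These rows were picked by symbol as RNAs shorter than a fragment of a total RNA library, and the length was not checked for every row. Of the short RNA rows, 92 were listed at 0 in one group and at 1 FPKM or more in the other, and no single short RNA is named here.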

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

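Leaving out short RNA rows, the 10 FPKM filter and the same sum for list medians were chosen after the data were seen. Over these and the alternatives chosen beforehand, 1441 of 1459 values of named genes stayed within their half-width and 18 moved further. The 18 came with smaller pseudocounts, and 0 of those with separate intervals reversed. Much of this was fixed in advance, because a filter or leaving out other rows cannot change a gene's difference. That holds for 169 values without a filter, 149 at 5 FPKM, 127 at 10 FPKM and 169 without short RNA rows. A pseudocount cannot reverse a sign either, so only the scalings could. Of 221 list medians 204 stayed within their bootstrap interval and 17 left it, and the 37 without short RNA rows could not change. The sign differed in 11 of the 221, for 9 lists under quantile normalization and for ERK output also at the same sum and the same median, and 1 of these lists, the cytosolic ribosomal proteins, lay outside the middle 95% of random lists in the main setting. Of 30 counts 22 stayed within 1.5 times the main count. The number of rows lower by at least 2-fold, 86, became 151 with a pseudocount of 0.1 and 176 with 0.01, which shrink low values less, 57 at 10 FPKM or more and 33 without short RNA rows, where the number of higher rows went from 223 to 116. Rows lower with separate intervals, 446, became 283 at 5 FPKM and 192 at 10 FPKM, and higher rows, 534, became 298 at 10 FPKM, with fewer genes entering. The ribosome biogenesis median of 0.123 became 0.093 at the same sum, 0.095 at the same median and 0.041 under quantile normalization. The cytosolic ribosomal protein median of 0.042 reversed to -0.059 under quantile normalization; the cause was not tested. Of 37 lists, 5 crossed the limits of the middle 95% of random lists under quantile normalization, 2 of 36 at 5 FPKM, 1 without short RNA rows and 0 at the same median or with a pseudocount of 0.1.

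No paired analysis was possible because the columns hold 1 estimate with bounds per group and carry no library values. The limma fits without trend or with robust moderation, the replicate block, camera with an estimated correlation, fry and leaving out each library were not run for the same reason. Depth was unknown, and precision was lowest under 1 FPKM.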

Other observations

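Tests on the columns of each group, on rows listed at 0 and on scaling were chosen after the result was seen; those on aryl hydrocarbon receptor targets and gene length were fixed before it. The genes named in the next 2 paragraphs were chosen after their values were seen, from the 40 genes in each direction that belong to no list, have separate intervals and lie furthest from control.

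The p53 list held 40 genes, so a gene outside the lists may still be a p53 target. Genes outside the lists that were higher with BMH-21 with separate intervals included the following. IL24, a cytokine of the IL-10 family, was 4.45-fold higher (log2 difference 2.07 ± 0.46), TNFSF9, the ligand of the receptor 4-1BB, 4.20-fold (1.96 ± 0.40), and SECTM1 4.62-fold (2.04 ± 0.38). CIITA, the master regulator of MHC class II genes, was 2.97-fold higher (1.44 ± 0.35). PTGS2, the inducible cyclooxygenase, was 8.41-fold higher (1.44 ± 0.26), at 2.54 FPKM against 0.303 FPKM (bounds 0.190 to 0.415). Its ratio is imprecise at that control level, and the pseudocount of 1 narrows its half-width. The death receptor gene TNFRSF10A was 2.68-fold higher (1.31 ± 0.38) and PIDD, a death domain protein, 2.60-fold higher (1.26 ± 0.37). SAT1, which breaks down polyamines, was 3.14-fold higher (1.63 ± 0.38), and SLC30A1, a zinc exporter, 3.24-fold higher.

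Among genes lower with BMH-21, H2AFX, the histone variant phosphorylated at DNA breaks, was 2.15-fold lower (-1.10 ± 0.37). PIM1, a survival kinase, was 2.55-fold lower (-1.09 ± 0.37), and SLC19A1, the reduced folate carrier, 2.28-fold lower (-1.04 ± 0.40). ITGB3, an integrin subunit, was 1.99-fold lower (-0.98 ± 0.37), PRRX1, a mesenchymal homeobox factor, 2.14-fold lower (-1.04 ± 0.37), and SLFN11, which blocks stressed replication forks, 2.19-fold lower (-1.01 ± 0.35).

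CYP1A1, CYP1B1 and TIPARP, all targets of the aryl hydrocarbon receptor, were higher with BMH-21, by 100-fold, 11.7-fold and 3.75-fold. A common scaling factor is argued against as the source, since it would move all genes alike, and the 95th percentile of the absolute log2 difference of genes other than short RNAs was 0.60, against 1.86 ± 0.36 for TIPARP. An earlier test, that CYP1B1 kept a log2 difference of at least 2.86 under 3 other scalings, decides nothing, because these moved the median of all genes by at most 0.05. A candidate explanation is that targets of this receptor were higher as a group: the 9 other measured targets of a list written before their values were seen had a median of 0.65, at percentile 100 of random lists, whose middle 95% ran from -0.15 to 0.23. Of these 9, 5 were higher with separate intervals, including the receptor's repressor AHRR (1.39 ± 0.66), and LMCD1 was lower (-0.76 ± 0.39). NQO1, a further target, was left out of the 9 because its value had been seen before. It was 1.46-fold higher (0.55 ± 0.37) with separate intervals. Without SLC7A5 and STC2, which also belong to the ATF4 list, 7 genes had a median of 0.19 at percentile 93.0. The group result of these 9 therefore needs SLC7A5 and STC2 to lie outside the middle 95% of random lists. Both lie above the median, so leaving them out must lower it, whatever the reason. Of the 7 genes, AHRR, HES1 (0.77 ± 0.38) and ABCG2 (0.65 ± 0.28) were higher with separate intervals. LMCD1 was lower, and NFE2L2, NEDD9 and PLAT overlapped. A set that includes NQO1 was not tested.

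The columns titled as replicates 1 to 3 may hold an estimate and its bounds. The share of row and group pairs with the first column at the midpoint of the others was 99.9408%, which separate libraries would not give. Where the second column was 0, the third was at least 2 times the first in 99.9312% of pairs, as a lower bound stopped at 0 needs. Whether the bounds include the variation between the 3 libraries stays open, and no biological explanation was tested.

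In 92 rows the estimate was 0 in one group, 56 times in control and 36 times in BMH-21, and 1 FPKM or more in the other. A candidate explanation is that these are genes shorter than a sequenced fragment, whose FPKM is poorly estimated: 100% of the 82 such rows with an annotated length had no transcript of 200 nt or more, against 2.39% of all measured genes with a length. The deposited interval of the group above 0 was narrow all the same, with a median half-width of 8.87% of the estimate. A difference in the small RNAs themselves was not tested and stays open.

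A hypothesis that long genes would be lower with BMH-21, as a block of transcript elongation could give, was tested over 10919 genes, 85.6% of those other than short RNAs. Spearman's rho between log2 difference and gene span was -0.012 across genes, which are not independent replicates. The longest 10% of genes had a median of -0.03 and the shortest 10% a median of -0.01, which argues against a trend over all spans. From the 10% of genes with a median span of 27604 nt to the longest, at 244519 nt, the medians went down from 0.06 to -0.03, so a small difference among long genes stays open.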
